A study of Mus musculus with 2 samples.

How the data were processed

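H3K27ac, the acetylation of lysine 27 of histone H3 that marks active promoters and enhancers, was measured by ChIP-seq in stomach of mouse embryos at embryonic day 16.5. The series holds 1 group of 2 libraries that the labels call biological replicates, from pooled embryos of both sexes of a C57BL/6 type strain. Replicate 2 was pooled from 41 embryos, and the number for replicate 1 is not given in the labels. Per the labels, fragments were 300 to 500 bp long. No second condition, tissue or age is in the design, so the peak sets were described, the replicates were compared with each other and gene lists were compared with other genes of the same tissue.

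The authors deposited 4 peak lists on mm10: 1 called on each replicate, 1 called on both replicates together (pooled) and 1 of peaks called replicated. Per the file headers and descriptions, the list of replicate 1 was derived from its alignments and 2 further inputs, the list of replicate 2 from its alignments and 1 further input, and the pooled list from both alignments and 2 further inputs. What those inputs are, the aligner, the peak caller and its version are not given in the sources used here. Each peak carries a fold enrichment, which is a linear ratio deposited by the authors, and −log10 of a p-value and of a q-value, also deposited by the authors, as well as the offset of its summit. Fold, p and q are the authors' own values per peak. They were used only to describe, rank or filter peaks within a list, never as a change between lists. The lowest −log10 p in the lists lay between 2.02 and 2.05, so peaks weaker than that are not seen. Read depth is unknown from these files, so no interval that needs read counts is given, and a gene without a peak is a gene without a listed peak, not a gene shown to lack the mark.

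Gene starts were taken from the GENCODE M21 annotation of the GRCm38 assembly, whose chromosomes match mm10; no peak ran past a chromosome end. Peaks on scaffolds outside chromosomes 1 to 19, X and Y (7, 10, 11 and 8 peaks in the lists of replicate 1, replicate 2, pooled and replicated) were left out after the count of peaks per list. A gene was called marked when a peak overlapped 1000 bp on either side of any annotated start of its 21829 protein-coding genes (54322 starts). Where several peaks did so, the 1 with the highest fold gave the gene's value. A peak at a shared start counts for each gene there. Coordinates are 1-based on mm10.

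Peaks of the replicates were called shared when the overlap covered at least 50% of either peak. The expected share came from 100 circular shifts of the other list within chromosomes, which allow a smallest one-sided permutation p of 0.0099. Folds of matched peaks were compared by Spearman's and Pearson's correlation across peaks, without a p because peaks are not independent replicates. Genes marked in 1 library only were compared by an exact two-sided McNemar test. Peaks were sorted into promoter (any overlap with a start window), and otherwise by midpoint into exon, intron and intergenic, against 100 random placements outside assembly gaps. The number of marked members of 33 gene lists was compared with all other protein-coding genes by Fisher's exact test, two-sided. Peaks outside start windows (distal) were given to the nearest start within 100 kb, and the median number per list (the mean where the median was 0) was compared with 10000 random lists matched on the tenth of the genome length nearest to each gene (1000 lists for the olfactory and vomeronasal receptors). Distal peaks outside 2.5 kb of any start were joined within 12.5 kb and ranked by the sum of fold times length, with the elbow of the ranked curve at slope 1. In 500 bp windows at summits of distal peaks, the share with each of 29 consensus sequences was compared with windows 5 to 20 kb away outside all peaks, matched on GC in steps of 1%, by Fisher's exact test. All families were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Genes and windows are not replicates: these tests describe this tissue pool, and the replicate check is the repeat on each library's own list.

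The lists covered gastric and other epithelia, mesenchyme, smooth muscle, interstitial cells of Cajal, enteric nerves, endothelium, blood cells, mesothelium, other organs that a dissection could carry over, signalling pathways, Hox genes and receptors silent outside sensory organs. The lists, consensus sequences, tests and most alternatives were set before the data were examined. Named genes follow a rule also set then: per list up to 4 members with the highest start-peak fold, plus the unmarked or the marked members where these were 5 or fewer, the genes nearest to the 20 top stitched domains, the genes at the 10 widest start peaks and at the 5 highest start peaks of each library with no peak in the other, and every Hox gene. Of the list symbols, 1 (Ahsp) was not found, and Cblif was found under its older symbol Gif.

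Alternatives were a q of at most 0.01, other overlap rules, the same number of top peaks per library, start windows of 500 bp and 2.5 kb, only the 5' end of each gene, the pooled list, each library's own list, a limit of 50 kb, stitching within 5 kb, ranking by covered length and 200 bp motif windows. Added after the data were seen were a background without olfactory and vomeronasal receptors, motif controls matched also on repeats or CpG, and a set of replicated peaks overlapped by peaks of both libraries. The overlap, list, distal, stitching and motif steps were tested on simulated data. Of 20000 simulated peaks 40.6% were planted as shared and 41.0% were found, and independent sets gave a permutation p of 0.119. For gene lists among 21829 genes, 10 of 10 lists planted higher and 4 of 10 planted lower were recovered, with 1 of 100 unchanged lists called. For distal counts, 10 of 10 planted lists were recovered and 0 of 20 unchanged lists were called. All 30 planted clusters of peaks lay above the elbow, among 119 regions so called. All 3 motifs planted in 3% of 20000 windows were called, and 0 of 26 others. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.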

Results

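The acetylated regions of the fetal stomach were mapped in 2 pools of embryos at embryonic day 16.5. The list of replicate 1 held 98252 peaks and that of replicate 2 held 112990. They covered 47.4 and 57.8 Mb, with median widths of 305 and 322 bp and a median fold over background of 3.77 and 4.08. A q of at most 0.01 was reached by 81.2% and 87.6% of them. The pooled list held 121678 peaks, and the authors' replicated list held 75487 of these same peaks, with a median width of 528 bp and a median fold of 4.51. The rule by which the authors called a peak replicated is not known, and 21.1% of the replicated peaks on chromosomes were not overlapped, over at least 50% of either peak, by a peak of both libraries. All 59585 pooled peaks on chromosomes that were so overlapped were in the replicated list. Read depth is unknown from the peak lists. Unless stated otherwise, values below are for the replicated list, and folds are the authors' values in that list.

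The highest fold at any start was at Sp3, a zinc finger transcription factor (chromosome 2, 72978435 to 72981278, fold 64.1), and at a peak shared by Brd2, a reader of acetylated histones, and H2-DMa (chromosome 17, 34119410 to 34124175, fold 61.7); these genes were singled out after their values were seen. The widest start peak spanned 19279 bp at Lsp1 on chromosome 7 (142470051 to 142489329, fold 20.4). Next came Myh9, the heavy chain of non-muscle myosin (11996 bp), Fam129b (11911 bp), Zmynd8, a chromatin reader (11108 bp), Tmbim1 (10055 bp) and Hic1, a transcriptional repressor (9969 bp). The other wide peaks lay at Hoxb3 (9769 bp), Msh5 and Clic1 (9646 bp), Meis2 (9208 bp) and Id1 (9178 bp).

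The first comparison asked how far the replicates hold the same acetylated regions and the same marked genes. Strong regions were shared almost throughout: in the top decile by fold, 99.97% of replicate 1 peaks and 99.9% of replicate 2 peaks were overlapped by the other list, against 43.0% and 27.3% in the lowest decile. Over all peaks the shares were 69.3% for replicate 1 and 55.9% for replicate 2, against 3.05% and 2.63% after shifts (p = 0.0099 for both, permutation, one-sided, the smallest that 100 shifts allow). Across 59311 matched peaks the log2 folds had a Spearman rho of 0.711 and a Pearson r of 0.816. Peaks with no overlap at all in the other list were weak, with median folds of 3.19 (25091 peaks, replicate 1) and 3.48 (44492 peaks, replicate 2). Of these, 2379 and 4355 lay at starts. Only 383 and 793 genes were marked in that library alone, so a gene with such a peak need not be marked in 1 library only. The highest such peaks at starts were at Wdr19 (fold 6.96), Rprm (6.75), Gnpnat1 (6.51), Acadl and Tma16 (6.42 each) in replicate 1. In replicate 2 they were at Aoc3 (9.58), Ranbp10 with Tsnaxip1 (9.12), Dennd3 (9.0), Krt79 (8.91) and Phf7 with Bap1 (8.40).

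**Figure D1:**
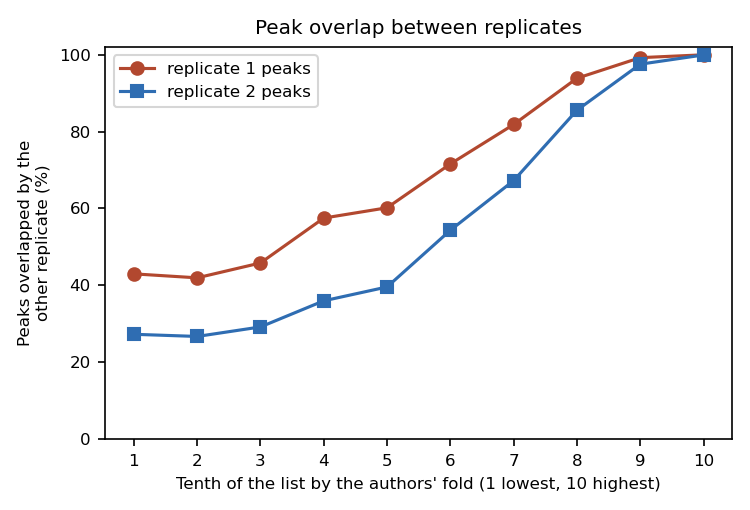
Share of each replicate's peaks (percent, vertical axis) overlapped by a peak of the other replicate over at least 50% of either peak, by decile of the list ranked on the authors' fold (horizontal axis). Each point is 1 decile of 1 list. The share climbs from 43.0% to 99.97% for replicate 1 and from 27.3% to 99.9% for replicate 2.

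At gene starts, 11986 of 21829 protein-coding genes were marked in both libraries, 8667 in neither, 383 in replicate 1 only and 793 in replicate 2 only, so that 94.6% of genes were in the same state. The excess in replicate 2 was beyond chance across genes (exact McNemar p = 1.9e-33); its size fell from 67.4% to 57.6% of these genes when the same number of top peaks was taken from each library. All 12 epithelial junction and keratin genes, all 14 smooth muscle genes, all 13 matrix genes, all 12 Hedgehog and all 12 Notch genes were marked in both. The endothelial list differed most: 11 of 17 genes were marked in both and 6 in replicate 2 only (exact McNemar p = 0.031, adjusted p = 0.5625). Those 6, named after their values were seen, were Cdh5, Tek, Tie1, Emcn, Sox7 and Sox17, which encode endothelial adhesion, angiopoietin signalling and transcription factor genes. In the Wnt list 4 genes were marked in replicate 2 only and 0 in replicate 1 only (exact McNemar p = 0.125, adjusted p = 0.75). No list passed the threshold after adjustment, and none could have. The most single-library genes in any list was 6, and even 6 on the same side gave an adjusted p of 0.5625. The test also takes an equal split as its null, while 67.4% of all single-library genes were in replicate 2. It therefore cannot tell whether a list departs from that general excess.

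The next question was where the mark lies. Promoters held 18818 replicated peaks, 24.9% against 3.55% expected from random placement, and their median fold was 7.12. Introns held 30870 peaks (40.9%, expected 36.6%) and intergenic sequence 23851 (31.6%, expected 57.4%), with median folds of 4.14 and 4.25. These 3 departures had p = 0.0099 (permutation, one-sided, the smallest possible). Exons held 2.57% against 2.45% expected (permutation p = 0.0198), and the direction turned with a 2.5 kb start window, where the share was 2.16%. On the X chromosome 348 of 948 genes (36.7%) were marked, against 11984 of 20698 (57.9%) on autosomes (Fisher's exact p = 1.3e-37, a comparison made after the values were seen), and only 2 genes were marked on Y. Copy number and read mapping on these chromosomes were not examined, so the counts alone do not show that their genes are less active.

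The lists then asked which cell types and pathways carried the mark at their gene starts, against 56.5% of all protein-coding genes (12334 genes). All 15 gastric endoderm transcription factors had a start peak (adjusted exact p = 0.0015), highest at Klf4 (fold 21.9), Sox2, which specifies the forestomach and gastric progenitors (19.5), Elf3 (19.1) and Grhl2 (19). Lowest were Foxa3 (5.12, on a peak shared with Sympk), Pdx1 (4.48) and Nkx6-3 (3.25), the last marked in replicate 2 only; these low members were singled out after their values were seen. All 12 epithelial junction and simple keratin genes were marked (adjusted exact p = 0.005), led by Krt19 (15.8), Cldn4 (15.7), Krt8 (14.9) and Cdh1, which encodes E-cadherin (14.6). Of the stratified squamous genes, which line the mouse forestomach, 11 of 12 were marked (adjusted exact p = 0.031), with Perp (17.7), Sfn (10.6), Dsg3 (8.22) and Krt15 (8.12) highest and Ivl, a late cornification gene, without a peak. Sprr3 (2.58) was marked in replicate 1 only, and the list lost its call with replicate 2 alone, with 500 bp start windows, with only the 5' end of each gene, for peaks overlapped by both libraries and without receptors in the background.

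Genes of differentiated gastric secretion stood on the other side. Only 3 of 15 gastric secretory genes had a replicated start peak (adjusted exact p = 0.014), all with low folds: the trefoil factors Tff2 (3.80) and Tff1 (3.44), each listed by replicate 2 alone, and Bhlha15, the transcription factor of zymogenic cells (3.75), listed by replicate 1 alone. No gene of the list was marked in both libraries. The proton pump subunits Atp4a and Atp4b, the pepsinogen gene Pgc and the mucin genes Muc5ac and Muc6, named after their values were seen, had none. Of the enteroendocrine genes only Isl1 (11.1) of 15 was marked (adjusted exact p = 0.00063); Isl1 also acts in other cell types.

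Most genes of the mesenchyme and muscle lists were marked. Of the stomach mesenchyme transcription factors, 13 of 15 had a start peak (adjusted exact p = 0.031), highest at Meis2 (fold 31.8; chromosome 2, 116059631 to 116068838), Nr2f2 (27.2), Foxf1, a Hedgehog target of gut mesenchyme (26.4), and Nr2f1 (23.4). Hand1 and Nkx2-5 had none, and this list lost its call with the list of replicate 2 alone, with start windows of 500 bp or 2.5 kb, with only the 5' end of each gene and without olfactory and vomeronasal receptors in the background. All 14 smooth muscle genes were marked (adjusted exact p = 0.0024), led by Smtn (18.3), the enteric actin gene Actg2 (18.1), Tpm2 (17.5) and Myh11, the smooth muscle myosin (17.2). All 13 extracellular matrix and fibroblast genes were marked (adjusted exact p = 0.0039), with Col1a1 (21.8), Sparc (21), Col3a1 (20.5) and Dcn (16.8) highest. All 6 genes of interstitial cells of Cajal and their relatives were marked, among them Etv1 (23), the pacemaker channel gene Ano1 (13.9), Pdgfra (13.4) and Slitrk6 (7.86), but 6 genes did not pass the threshold (adjusted exact p = 0.056).

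Minor and foreign cell types gave mixed or low shares. Endothelial genes were marked in 14 of 17 (adjusted exact p = 0.065), with Fli1 (9.45), Eng (9.33), Esam (5.87) and Tal1 (5.49) highest and Sox17, Tie1 and Sox7 unmarked; with the list of replicate 2 alone all 17 were marked and the list passed the threshold. Enteric nervous system genes were marked in 9 of 20 (adjusted exact p = 0.43), led by Erbb3 (18.6), Hand2 (13.7), Th (5.54) and Ednrb (4.74). Leukocyte genes were marked in 8 of 15 (adjusted exact p = 0.80), with Runx1 (11.2), Cd68 (5.31), Lyz2 (4.94) and Laptm5 (4.03) highest. Mesothelial genes were marked in 4 of 8 (adjusted exact p = 0.76), namely Upk1b and Upk3b (3.84 each), Bnc1 (3.66) and Msln (3.54). Msln was listed by replicate 2 alone. Erythroid genes were marked in 2 of 12 (adjusted exact p = 0.014), Klf1 (9.79) and Gypa (5.06); with the list of replicate 1 alone 25% were marked and the list no longer passed. The near-identical globin copies on this list are uncertain where reads map to both.

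Organs next to or far from the stomach were mostly unmarked. None of 10 lung epithelial genes had a start peak (adjusted exact p = 0.0015). Liver genes were marked in 3 of 15 (adjusted exact p = 0.014): Apoh (9.50), Trf (5.51) and Ttr (3.96), of which the first pair share their peak with a start of another gene; with the list of replicate 1 alone 26.7% were marked and the list no longer passed. Forebrain genes were marked in 3 of 15 (adjusted exact p = 0.014), with Bcl11b at 15.2, Dlx1 at 3.96 and Dlx2 at 3.25. Dlx2 was listed by replicate 1 alone. Germ cell genes were marked in 2 of 11 (adjusted exact p = 0.026), Dazl (7.87) and Tdrd1 (3.80). The germ cell call was lost with only the 5' end of each gene and for peaks overlapped by both libraries. Pancreas genes were marked in 5 of 15 (adjusted exact p = 0.14; Nkx6-1 5.85, Rbpjl 3.91, Nr5a2 3.79, Cpa2 3.77, Cpa1 2.97; the Rbpjl peak is shared with Matn4). Heart muscle genes were marked in 3 of 12 (adjusted exact p = 0.056; Myh7 6.80, Myl7 4.66, Tnnt2 4.59) and skeletal muscle genes in 4 of 14 (adjusted exact p = 0.073; Mylpf 7.83, Tnni2 7.32, Actn3 4.37, Tnnt3 3.49; the Mylpf and Actn3 peaks are shared with other genes). Kidney genes were marked in 3 of 11 (adjusted exact p = 0.085; Slc34a1 8.15, Eya1 5.67, Nphs1 3.70, shared with Kirrel2). Intestinal genes were marked in 8 of 16 (adjusted exact p = 0.66), with Mttp highest (38.6, a peak shared with the start of Trmt10a), then Satb2 (7.31), Hnf4g (6.76) and Vil1 (5.67). Olfactory and vomeronasal receptors were marked in 7 of 1463 (0.478%), far below the 60.5% of other genes (Fisher's exact test, p below what the computer resolves).

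Signalling and general lists were mostly high. All 12 Hedgehog genes were marked (adjusted exact p = 0.005), with the receptor Ptch1 at 31.6, Smo at 24.1, Gas1 at 23.2 and Gli3 at 23.1. All 12 Notch genes were marked (adjusted exact p = 0.005), led by Jag1 (29.8), Hes1 (28.5), Lfng (27.8) and Notch2 (21). BMP genes were marked in 12 of 14 (adjusted exact p = 0.048), with Id2 (26.7), Smad6 (25.1), Smad7 (19.4) and Id1 (18.5) highest and Msx1 and Msx2 unmarked. Wnt genes were marked in 8 of 12 (adjusted exact p = 0.63), with Fzd2 (24.3), Axin2 (19.7), Wnt5a (11.8) and Wnt4 (10.5) highest and Lef1, Dkk2, Wnt11 and Tcf7 unmarked; with replicate 2 alone 91.7% were marked and the list passed. Housekeeping genes were marked in 18 of 18 (adjusted exact p = 0.00046; Actb 52.7, Ywhaz 49.7, Tuba1b 29.6, Hmbs 29.5) and cell cycle genes in 15 of 16 (adjusted exact p = 0.005; Ccnd2 19.5, Mcm6 15, Plk1 14.8, Cdk1 14.5; Bub1 unmarked). In all, 12 lists lay above other genes, 9 below and 12 did not pass. Without the olfactory and vomeronasal receptors in the background, the heart muscle and skeletal muscle lists passed as lower, and the squamous, mesenchyme, BMP and Hox 1 to 5 lists no longer passed. Each of these last 4 also lost its call with the list of replicate 2 alone (BMP and Hox 1 to 5 with that of replicate 1 alone too).

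**Figure D2:**
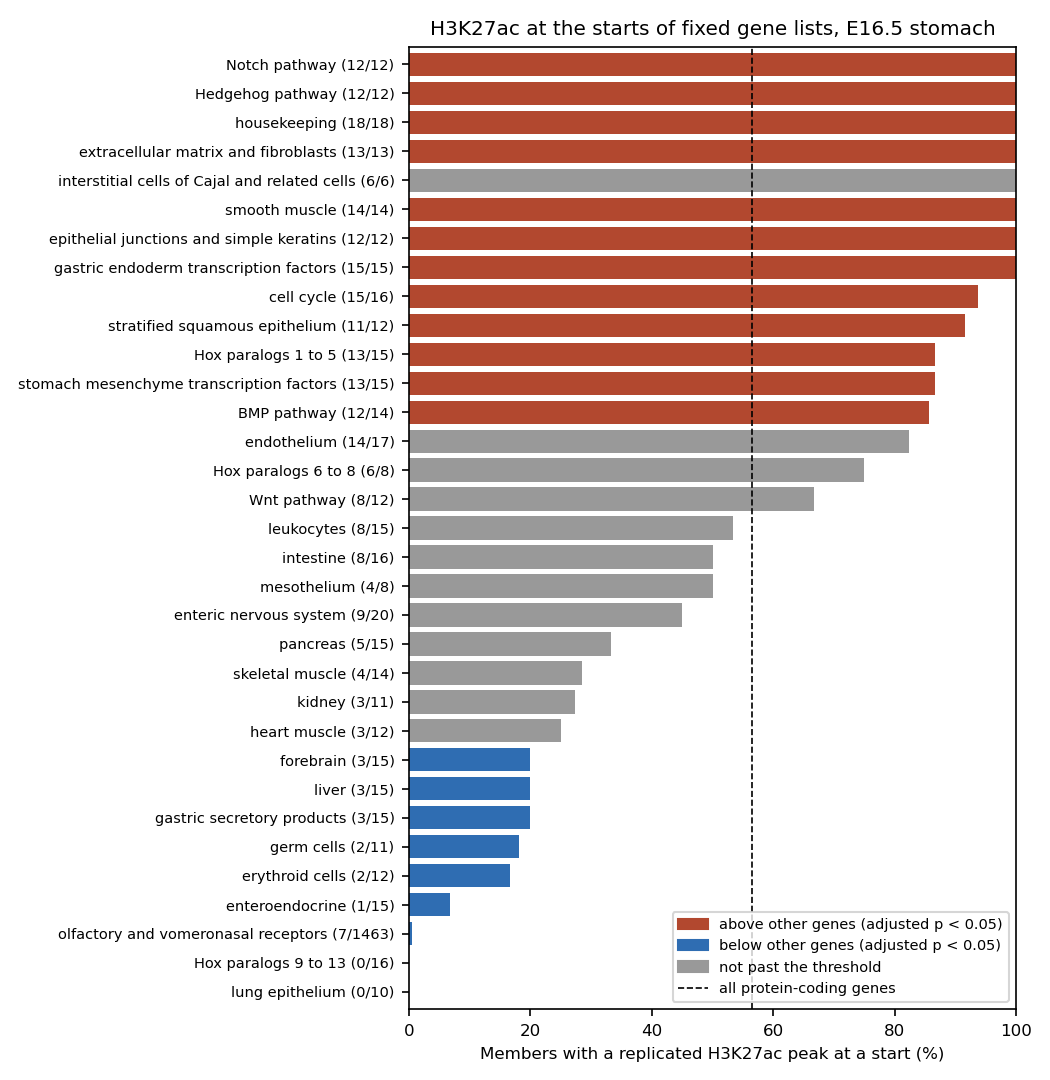
Share of each list's genes with a replicated H3K27ac peak within 1000 bp of a start (percent, horizontal axis), with marked and all members in brackets. Red and blue bars passed Fisher's exact test after adjustment, grey bars did not, and the dashed line is the 56.5% of all protein-coding genes. Lung epithelium and Hox paralogs 9 to 13 have no marked member.

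The Hox genes, which pattern the body from head to tail, split by paralog number. Of paralogs 1 to 8, 19 of 23 genes were marked, and of paralogs 9 to 13, 0 of 16 (Fisher's exact p = 1.5e-07, a comparison of these sets made after the values were seen). As fixed lists, paralogs 1 to 5 were marked in 13 of 15 (adjusted exact p = 0.031, a call kept with the pooled list but lost under every other alternative), paralogs 6 to 8 in 6 of 8 (adjusted exact p = 0.55) and paralogs 9 to 13 in 0 of 16 (adjusted exact p = 2.7e-05). Hox genes lie side by side in clusters and some neighbours share a peak. The tests treat them as independent, so the p-values for Hox genes may be too small. In the Hoxb cluster, Hoxb4 (fold 22.5), Hoxb2 (22), Hoxb3 (19.2), Hoxb5 (11.2), Hoxb6 (10.9) and the shared peak of Hoxb7 and Hoxb8 (11.5) were marked, while Hoxb1, Hoxb9 and Hoxb13 were not. In the Hoxa cluster the fold was 20.5 at Hoxa1, 15.2 at Hoxa2, 10.2 at Hoxa3, 17.7 at Hoxa4, 6.64 at Hoxa5, 6.24 at Hoxa6 and 6.16 at Hoxa7, and Hoxa9 to Hoxa13 had none. Hoxc4 (7.35), Hoxc5 (22.5) and Hoxc6 (8.77) were marked and Hoxc8 to Hoxc13 were not. The Hoxd cluster carried only weak peaks at Hoxd3 (3.66) and Hoxd4 (2.57), and none at Hoxd1 or Hoxd8 to Hoxd13. Hoxd8 had a start peak in each library's own list (folds 3.69 and 4.39) but no replicated one, and Hoxd4 had one in neither library's own list. Hoxb9 had one in the list of replicate 1 alone (2.74), the only such gene of paralogs 9 to 13.

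**Figure D3:**
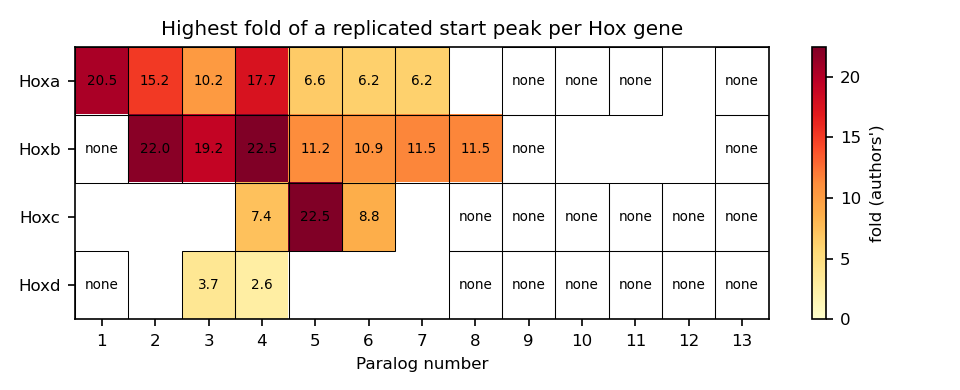
Fold of the highest replicated start peak of each Hox gene, with clusters as rows and paralog numbers as columns. Outlined cells are genes in the annotation, colour and number give the authors' fold, and "none" means no replicated peak. In the replicated list marked genes end at paralog 7 in Hoxa, 8 in Hoxb, 6 in Hoxc and 4 in Hoxd, though Hoxd8 is marked in each library's own list.

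Distal peaks, which include candidate enhancers, were counted around the same lists to ask which genes have many. Around gastric endoderm transcription factors the median was 10 distal peaks per gene, against 1.11 in random lists of like territory (adjusted permutation p = 0.004), with 35 at Gata4, 31 at Grhl2, 29 at Klf5 and 15 at both Sox2 and Foxa1. Matrix genes also had a median of 10 (expected 1.29, adjusted permutation p = 0.0033), mesenchyme factors and Hedgehog genes 8 (expected 1.63 and 1.30, adjusted permutation p = 0.019 and 0.0081), and Notch genes 7 (expected 1.02, adjusted permutation p = 0.0092). Epithelial junction genes, smooth muscle genes and endothelial genes each had 6 (expected 0.333, 0.46 and 0.78, adjusted permutation p = 0.0022, 0.0022 and 0.0047). Squamous genes had 4 (expected 0.261, adjusted permutation p = 0.0022), Hox paralogs 1 to 5 had 2 (expected 0.0249, adjusted permutation p = 0.0044) and Hox paralogs 6 to 8 a mean of 1.38 (expected 0.323, adjusted permutation p = 0.034). Hox paralogs 9 to 13 had a mean of 0 (expected 0.749, adjusted permutation p = 0.034) and olfactory and vomeronasal receptors 0.0328 (expected 1.24, adjusted permutation p = 0.0081). The other 20 lists did not pass. The random lists were matched on territory but not on having a start peak. A distal peak lay nearest to 58.9% of marked genes and to 24.0% of genes without a start peak. The share of marked genes in a list may thus contribute to its call. With the list of replicate 2 alone Hox paralogs 6 to 8 no longer passed, and with that of replicate 1 alone BMP genes did (median 8). Mesenchyme factors and Hox paralogs 9 to 13 lost their call with a 2.5 kb start window and for peaks overlapped by both libraries. Hox paralogs 1 to 5 lost it for those peaks and with only the 5' end of each gene, endothelial genes for those peaks and with a 50 kb limit. Hox paralogs 6 to 8 also lost it with either other start window, a q of at most 0.01 and the pooled list. Housekeeping genes gained one with 500 bp windows, the 5' end and the pooled list, and BMP genes with the 50 kb limit. The nearest start is not always the target: of 47831 distal peaks within 100 kb of a start, 7141 (14.9%) lay nearest to a gene without a start peak.

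Distal peaks were joined into 18624 regions, of which 630 (3.38%) lay above the elbow and held 34.9% of the summed fold times length and 24.9% of the covered length. Only starts of protein-coding genes were left out, so start peaks of noncoding genes count as distal here. For example, the highest fold in the region of rank 7, 37.0, is that of the Neat1 start peak. The top region spanned 416 kb between and within Rad51b and Zfp36l1, an RNA-binding protein gene, with 129 peaks (chromosome 12, 79732315 to 80148270). The second (chromosome 2, 30636202 to 30726296, 25 peaks) had its midpoint 86.2 kb from the nearest start, that of Cstad. The third lay over Tex44 and Nmur1 (chromosome 1, 86421226 to 86505948). The fourth (chromosome 18, 61609193 to 61695048, 19 peaks) is nearest to Il17b and contains the noncoding genes Carmn, Mir143 and Mir145a, known regulators of smooth muscle. Btg2, Zfp36l2 and Scyl1 followed, the last region holding the abundant nuclear RNAs Malat1 and Neat1, then Chd2, the retinoid receptor gene Rxra and Wasf2. Ranks 11 to 20 lay nearest to Irf2bpl, Syt2, Ski, Sik1, Ddc, Mrpl23 (a region holding the imprinted gene H19), Cuedc1, Rbpms, a regulator of smooth muscle splicing, Zmiz1 and Parva.

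Of 32 lists with a gene nearest to a region, 2 were more frequent above the elbow (Fisher's exact test). These were gastric endoderm transcription factors, with 5 of 13 genes (Elf3, Klf5, Foxa1, Foxa2 and Gata4), and matrix genes, with 5 of 13 (Col1a1, Col5a1, Pdgfrb, Col1a2 and Sparc), each 38.5% against 6.53% of other genes (adjusted exact p = 0.016). Mesenchyme factors (4 of 13) and Hox paralogs 1 to 5 (3 of 7) did not pass (adjusted exact p = 0.066 for both). Unlike the distal counts, this test was not matched on the genome length nearest to each gene, so that length may contribute. With the list of a single replicate 4 or 5 lists passed: mesenchyme factors with either, Hedgehog genes and Hox paralogs 1 to 5 with replicate 2 and epithelial junction genes with replicate 1. No list passed when regions were ranked by covered length. With stitching within 5 kb matrix genes lost their call, mesenchyme factors and Hedgehog genes gained one, and 8 of the 20 top genes were kept. For peaks overlapped by both libraries gastric endoderm factors lost theirs.

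The last comparison asked which transcription factor families' consensus sequences lie in distal peaks. These include start peaks of noncoding genes, so a site in them need not lie in an enhancer. In 500 bp windows at 56624 summits, FOX sites were in 8.37% of peak windows and 5.59% of control windows (log2 odds 0.63 ± 0.03, SE), AP-1 sites in 12.1% and 8.87% (0.50 ± 0.03), E-box CAGCTG sites in 31.7% and 25.7% (0.42 ± 0.02) and TEAD sites in 14.6% and 11.7% (0.36 ± 0.03). The SRF CArG box of muscle genes was in 2.86% and 2.23% (0.37 ± 0.05). Among sites in few windows, HNF1 was at 1.86 ± 0.46 (45 and 12 windows), NFI at 1.5 ± 0.35 (66 and 23), NRF1 at 0.94 ± 0.33 (56 and 29), GRHL at 0.69 ± 0.21 (123 and 76), and YY1 and GLI did not pass. ETS was at 0.58 ± 0.11. SP, HNF4, p63, KLF, SOX, MEF2, CTCF, homeodomain, GATA and MEIS sites were also higher, the last pair by only 0.08 and 0.07. RUNX (−0.12 ± 0.03) and NFY (−0.22 ± 0.03) sites were lower, RUNX not so with controls matched also on repeats (−0.0211 ± 0.03, adjusted exact p = 0.52). With those controls GATA (0.0161), NRF1 (0.26), CTCF (0.14) and homeodomain (0.03) sites lost their call. MEIS and TALE (−0.11, adjusted exact p = 1.7e-09) and GLI (−0.31, adjusted exact p = 0.017) were lower. Posterior HOX and CDX, NKX2, TCF and LEF, NR2F and CREB sites did not pass. CTCF lost its call with the list of either replicate alone and NRF1 with that of replicate 2. With each of these single lists 1 motif gained a call. With a q of at most 0.01, 2 motifs lost theirs, as did 1 motif for peaks overlapped by both libraries. In all 20 motifs were higher, 2 lower and 7 not called (Fisher's exact test, adjusted).

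The result depends on how far from the summit the window reaches. With 200 bp windows only 7 motifs were higher and 6 lower; FOX (0.46), E-box CAGCTG (0.31) and TEAD (0.22) stayed higher, and AP-1 (−0.10) did not pass and changed sign. AP-1 sites were most frequent 100 to 300 bp from the summit, at 3.22 per 10 kb, against 1.82 within 100 bp and 2.23 at 400 to 600 bp. FOX sites followed the same order (2.08, 1.43 and 1.80), as did CTCF sites (0.152, 0.0433 and 0.101), while E-box CAGCTG sites were densest within 100 bp (8.21, against 7.70 at 100 to 300 bp). These densities are of peak sequence alone, without controls or correction for GC. Peak windows held more GC in their middle 200 bp (50.3%) than over 500 bp (48.2%). That works against AT-rich FOX sites and for GC-rich E-box sites at the summit, so GC may contribute to their contrast.

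**Figure D4:**
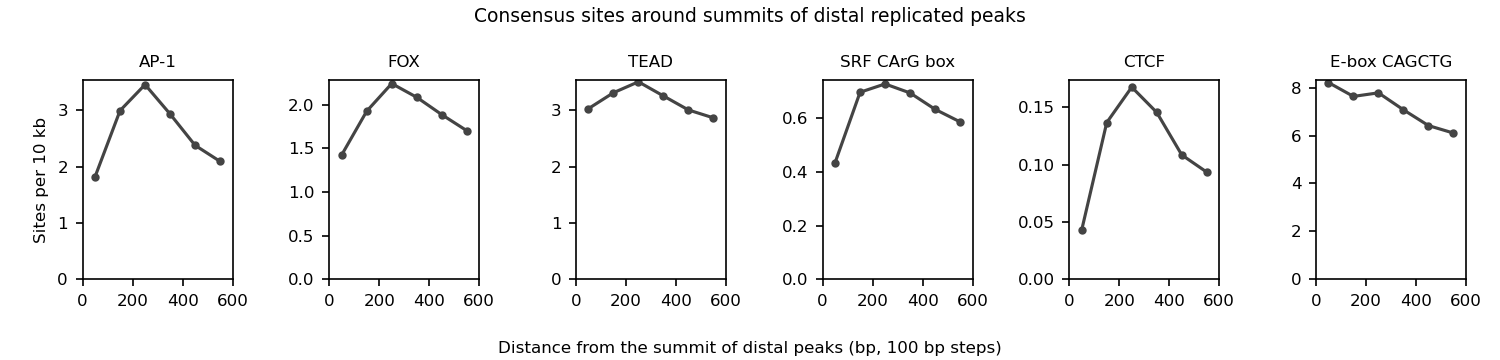
Consensus sites per 10 kb (vertical axis, a separate scale from 0 in each panel) by distance from the summit of distal replicated peaks (horizontal axis, bp), in 100 bp steps. Each point is the density over both sides of all summits, without controls or correction for GC. AP-1, FOX, TEAD, SRF and CTCF sites are densest beside the summit, and E-box CAGCTG sites at it.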

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

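All tests in this part were set down before their values were seen, except the pooled-only comparison of gene lists, which was chosen afterwards.

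A signal outside the comparisons lay in the pooled list, where 46188 peaks on chromosomes (38.0% of that list) are left out by the replicated list. They were weak, with a median fold of 2.85, and 9.51% lay at promoters. By the 50% overlap rule, all 59585 pooled peaks that met a peak of both libraries are in the replicated list. The left-out peaks thus held 0 of these. Of the left-out peaks 19873 (43.0%) met a peak of replicate 2 only, 9990 (21.6%) a peak of replicate 1 only and 16325 (35.3%) a peak of neither. They mark the start of 735 genes that have no replicated start peak, among them 3 of the 4 Wnt genes without one (Dkk2, Wnt11 and Tcf7, adjusted exact p = 0.022) and 2 of 1456 olfactory and vomeronasal receptors, fewer than among other genes (adjusted p = 1.6e-50). No other list passed, and the nearest were endothelial genes (2 of 3, adjusted exact p = 0.11) and leukocyte genes (3 of 7, adjusted exact p = 0.11). The 3 Wnt genes are also marked in the list of replicate 2 only, so they are part of the excess of replicate 2 below and not a separate result. The replicated list also held 8 peaks on scaffolds outside the chromosomes: 3 on unlocalised scaffolds of chromosome 4, 2 on those of chromosome X and 3 unplaced.

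More gene starts were marked in replicate 2 only (793) than in replicate 1 only (383). The longer list of replicate 2 does not account for all of it: with the same number of top peaks per library the share of replicate 2 was 57.6% (exact 95% interval 54.6 to 60.4), down from 67.4%, so list length may account for part. Wider peaks of replicate 2 alone do not account for all of it either. With the full lists the share was 65.5% (62.8 to 68.1) when the summit itself had to lie in the start window. List length and peak width were not removed together, so their joint part is not known. The lists also differ in strength, with a median fold of 4.08 in replicate 2 and 3.77 in replicate 1, and read depth is unknown. A q of at most 0.01 was reached by 87.6% and 81.2% of their peaks. The replicates differ too in the number of further inputs behind their lists and come from different pools of embryos. With 1 library each these differences cannot be separated here. No biological explanation was tested, because the design names no difference between the replicates.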

How the results depend on the processing

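The background without receptors, the extra motif controls and the set overlapped by both libraries were chosen after the data were seen. Of the summary results, 116 comparisons with an alternative kept their direction, their side of the threshold or their count within 1.5 times, 10 moved and 2 turned. The list and motif values kept theirs in 946 comparisons, with 67 weaker, 26 stronger and 10 turned. A change of direction where neither value was called counts as kept, as for CREB sites with 200 bp windows. For all that changed, the cause was not tested unless named.

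The replicate fold agreement (rho) was 0.766 with 50% of both peaks overlapping, against 0.711. The exon share fell below its expected value with a 2.5 kb start window (2.16%, expected 2.17%) and for peaks overlapped by both libraries (2.38%, expected 2.44%). Lists with fewer distal peaks numbered 1, not 2, under both of these settings: Hox 9 to 13 and mesenchyme genes lost their distal call under both, Hox 6 to 8 with the 2.5 kb window and Hox 1 to 5 and endothelial genes for peaks overlapped by both. Stitching within 5 kb kept 8 of the 20 top genes, lost the matrix list and gained the mesenchyme and Hedgehog lists above the elbow. Lists enriched above the elbow numbered 0 when ranked by covered length and 1 for peaks overlapped by both libraries (gastric endoderm factors lost), against 2, and 4 to 5 when either replicate was left out. With 200 bp windows 7 motifs were higher and 6 lower, and the log2 odds changed sign for HNF1 (−0.79), HNF4 (−0.0721), KLF (−0.31), SP (−0.53), AP-1 (−0.10), MEF2 (−0.15), CTCF (−1.39), NRF1 (−0.82), posterior HOX and CDX (−0.10) and CREB (−0.43, called under neither). MEIS and TALE sites changed sign with controls matched on repeats (−0.11) and became lower, as did GLI. RUNX, GATA, NRF1, CTCF and homeodomain sites lost their call there. With controls matched on CpG number NRF1, CTCF and homeodomain sites lost theirs. Without receptors in the background heart and skeletal muscle genes became lower at starts, and squamous, mesenchyme, BMP and Hox 1 to 5 genes lost their call. Leaving out a replicate gave 10 lists higher at starts, 7 to 9 lower, 10 to 12 higher in distal peaks and 19 to 20 motifs higher. At starts, erythroid, liver, BMP and Hox 1 to 5 genes lost their call without replicate 2, squamous, mesenchyme, BMP and Hox 1 to 5 genes lost it without replicate 1, and endothelial and Wnt genes gained one there. Hox 1 to 5 genes lost theirs under every other setting but the pooled list, and BMP genes under every one but the 5' end. Squamous genes lost it with 500 bp, the 5' end and peaks overlapped by both, mesenchyme genes with 500 bp, 2.5 kb and the 5' end, and germ cell genes with the 5' end and peaks overlapped by both. Enteric nerve genes became lower with 500 bp, and with the pooled list endothelial and Wnt genes became higher and heart, skeletal muscle and kidney genes lower.

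Read depth is unknown, which limits every statement on a start without a listed peak: with a q of at most 0.01, 10 lists were higher at starts, against 12, BMP and Hox 1 to 5 genes being lost.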

Other observations

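The tests of motif positions and of GC matching were chosen after the results for 200 bp windows were seen. The tests of repeats and CpG use controls added after the data were seen, but were set down before their own values were.

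Noncoding genes carried strong marks as well. Of 8058 long noncoding genes whose start lies away from every protein-coding start, 1339 (16.6%) had a replicated peak there, of which 22 had only peaks wide enough to reach a coding start as well (the highest peak did so for 6 of the 30 highest genes, and for none of those named here). The nuclear RNAs Neat1 (fold 37.0) and Malat1 (35.6), the snoRNA host Snhg8 (37.0) and Dnm3os, the host transcript of a mesenchymal microRNA cluster (30.9), were among the 30 highest. All were marked in both libraries, with folds in the lists of replicate 1 and replicate 2 of 30.5 and 32.5 at Neat1, 26.8 and 43.7 at Malat1 and 22.2 and 28.4 at Dnm3os. These genes were picked after their values were seen.

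Some genes had no replicated start peak but many distal peaks nearest to them. Wnt11 had 26, Fabp2, a gene of intestinal fatty acid uptake, 21, Scgb1a1, a lung secretory gene, 17, Pax8, a kidney factor, 10 and Nanos3, a germ cell gene, 8. Of 9495 genes without a start peak 2283 (24.0%) had a distal peak, against 58.9% of marked genes. These genes too were picked after their values were seen.

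Consensus sites were more frequent in distal peaks, and control windows held more repeats (25.2% against 14% of bases) and fewer CpG (6.32 against 7.04 per window). Repeats in the controls do not account for the pattern as a whole: with controls matched on GC and repeat share 15 of the 20 motifs kept their call, and the median log2 odds of all 20 was 0.28, against 0.37. CpG content does not either, as 17 kept it with matching on CpG number, with a median of 0.29. NRF1, homeodomain and CTCF lost the call with either matching and GATA with repeat matching, where MEIS and TALE turned lower (−0.11), so there these stay a candidate source. For CTCF the log2 odds was 0.23 ± 0.12 (SE) with CpG matching, against 0.26 ± 0.12 without it. Its lost call there alone does not point to CpG content. No biological explanation was tested, since the design has 1 group.

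Close to the summit, 4 motifs turned lower only with 200 bp windows: CTCF, posterior HOX and CDX, KLF and SP. GC matching of the narrow windows does not account for CTCF: with matching over 500 bp the middle 200 bp still held more GC in peaks than in controls (50.3% against 48.3%), which favours its GC-rich sites, and yet they stayed lower (−1.15 ± 0.25, SE, adjusted exact p = 7.5e-06). That GC difference works against AT-rich posterior HOX and CDX sites (−0.33 ± 0.04) and for GC-rich KLF and SP sites (−0.0485 and −0.14, from −0.31 ± 0.04 and −0.53 ± 0.10), so for these 3 GC matching cannot be told apart. A nucleosome under the summit with sites beside it stays open too: 3 of the 4 motifs, against 11 of all 29, were densest 100 to 300 bp away, by over 2 standard errors, but the 4 were picked for few sites at the summit.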
